A study of Homo sapiens with 18 samples.

How the data were processed

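Polyadenylated RNA was measured by sequencing in 18 libraries of human fibroblasts, 12 from IMR-90 ER:Ras cells in 4 groups and 6 from TIG-3 cells in 3 groups. Per the labels, libraries were made with a NEBNext Ultra II kit. The authors deposited, for each library, expected counts per gene from RSEM 1.3.1 on the genome build hg19, after trimming with Trim Galore 0.5.0. The aligner is not given in the sources used here. Expected counts are estimated reads per gene and are not normalised; 15.7% of the values above 0 were not whole numbers. Each of the files listed the same 26334 genes by RefSeq symbol. The reference at hand is of another genome build, so no coordinates are given.

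Expected counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, libraries were scaled with TMM, and genes were tested with the quasi-likelihood F test (glmQLFit, glmQLFTest), two-sided. P-values were adjusted by Benjamini-Hochberg over the genes tested, and an adjusted p under 0.05 counted as a call. A fit each was made to these sets of libraries: the 12 IMR-90 libraries (14163 genes, 7 residual degrees of freedom), the 6 TIG-3 libraries (14422 genes, 3) and all 18 libraries for the difference between the lines (14965 genes, 10). The biological coefficient of variation was 18.4% in the IMR-90 and 11.6% in the TIG-3 fit. The IMR-90 fit and the fit to all libraries held a term for the label set, the group of samples whose labels share a text, which sets the p300/CBP and FOXF1/2 knockdowns against controls 1 to 4 and the JUN knockdown against controls 5 and 6. Because the groups of a fit share an estimate of the spread, a knockdown with 2 libraries could be tested. CPM are counts per TMM-scaled library size. Standard errors were calculated from the test, as the absolute unshrunken log2 fold change divided by the square root of its F statistic. They stand beside log2 fold changes that edgeR shrinks slightly.

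Lists of genes were written before the data were examined, 24 in all, on secreted factors, signalling, the cell cycle, matrix, metabolism and markers of other cell types. The siRNA targets were read gene by gene and the other 23 lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation was the alternative, and no list passed with it in any comparison. A list's genes were counted by the adjustment over all genes and by one over the list alone.

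The comparisons, the gene lists, the alternatives and the rule for naming genes were also set before the data were examined. The rule named the 7 siRNA targets, and the 8 genes per direction with the largest change in each comparison (5 for the difference between the lines). These had an adjusted p under 0.05, an average log2 CPM of at least 4 and no overlap between the libraries compared, without classical HLA genes, noncoding RNA symbols, XIST and Y-linked genes. It also named the 2 most changed members of each list that passed and of 5 lists chosen in advance, and allowed any member of those 5. Overlaps between comparisons were set against independent calls and 20 simulations of unchanged groups with the same controls. A test with no senescent control in common in TIG-3, chosen after the data were seen, compared single libraries with glmLRT at the dispersions of the TIG-3 fit.

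For a gene with 0 counts in a group, a bound was taken against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% interval from an exact binomial test. A floor of 3 counts corresponded to between 0.104 and 0.186 CPM in a single library. Intervals and floors cover counting error only.

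The gene and list tests were tested on simulated data, in 5 draws per comparison with 200 genes changed, 100 by 2-fold and 100 by 4-fold, among 13845 to 14430 genes. On average the 2-fold changes were recovered in 66.4% of cases in the p300/CBP comparison, 64.8% for FOXF1/2 in IMR-90, 51.0% for JUN, 84.8% for etoposide, 85.4% for FOXF1/2 in TIG-3 and 34.6% for the difference. The 4-fold changes were recovered in 97.6%, 96.0%, 93.0%, 98.2%, 97.6% and 85.2%. False calls made up 5.21%, 5.18%, 4.74%, 9.90%, 9.41% and 4.89% of calls, so in the TIG-3 fit the share was higher than the 5% set. A planted list of genes raised 2-fold was called in all 5 draws of each comparison. Unchanged lists were called 2 times of 110 in the JUN comparison and 0 times in the others. Counts were drawn for each gene on its own, so these lists held no correlation between genes.

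The alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts or a CPM of at least 1 in 2 libraries, a minimum absolute log2 fold change of 1, no term for the label set, only the groups compared, controls 1 and 2 or 3 and 4 alone, a term for the replicate number, and leaving out each library in turn. Scaling by total counts alone and removal of each library's trend of log2 CPM against transcript length (lowess, span 0.3) were added after the data were seen. Alignments and raw reads were not used here.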

Results

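RNA levels were measured in 18 sequencing libraries from a pair of human lung fibroblast lines, IMR-90 and TIG-3. The IMR-90 cells carried ER:Ras, a RAS oncoprotein that 4-hydroxytamoxifen switches on, and were senescent after 6 days in 100 nM of the drug. These libraries came from 6 controls, 2 knockdowns of p300 and CBP, 2 knockdowns of FOXF1 and FOXF2, and 2 knockdowns of JUN-family genes. TIG-3 cells gave 2 proliferating controls, 2 controls made senescent with 100 uM etoposide for 2 days followed by 9 days without it, and 2 senescent FOXF1/2 knockdowns. The label text of IMR-90 controls 1 to 4 matched that of the p300/CBP and FOXF1/2 knockdowns, and the text of controls 5 and 6 matched that of the JUN knockdown. Each knockdown was therefore set against the controls described with it. Total counts per library ranged from 16153400 to 23402400 in the IMR-90 controls, 16419800 to 16604000 in the p300/CBP, 16724100 to 17415700 in the FOXF1/2 and 25894200 to 27364900 in the JUN knockdown. In TIG-3 they ranged from 21337300 to 27290800 in proliferating cells, 21423300 to 24328000 in etoposide-treated cells and 18524300 to 28764500 in their FOXF1/2 knockdown. The title of the JUN group names JUN and JUND, while its treatment text also lists JUNB. The proliferating TIG-3 controls carry a senescent cell type in the labels, although MKI67, a proliferation marker, was at 86.6 ± 16.0 CPM there and at 12.2 ± 7.69 after etoposide (mean ± SD, n = 2 each). CPM, which are counts scaled to the size of the library, are given as means ± SD over the libraries of a group. Changes are log2 fold changes with their standard error (SE), and p-values were adjusted over all genes tested. Replicates are not said to come from separate cultures, so the p-values measure only the spread between these samples.

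**Figure D1:**
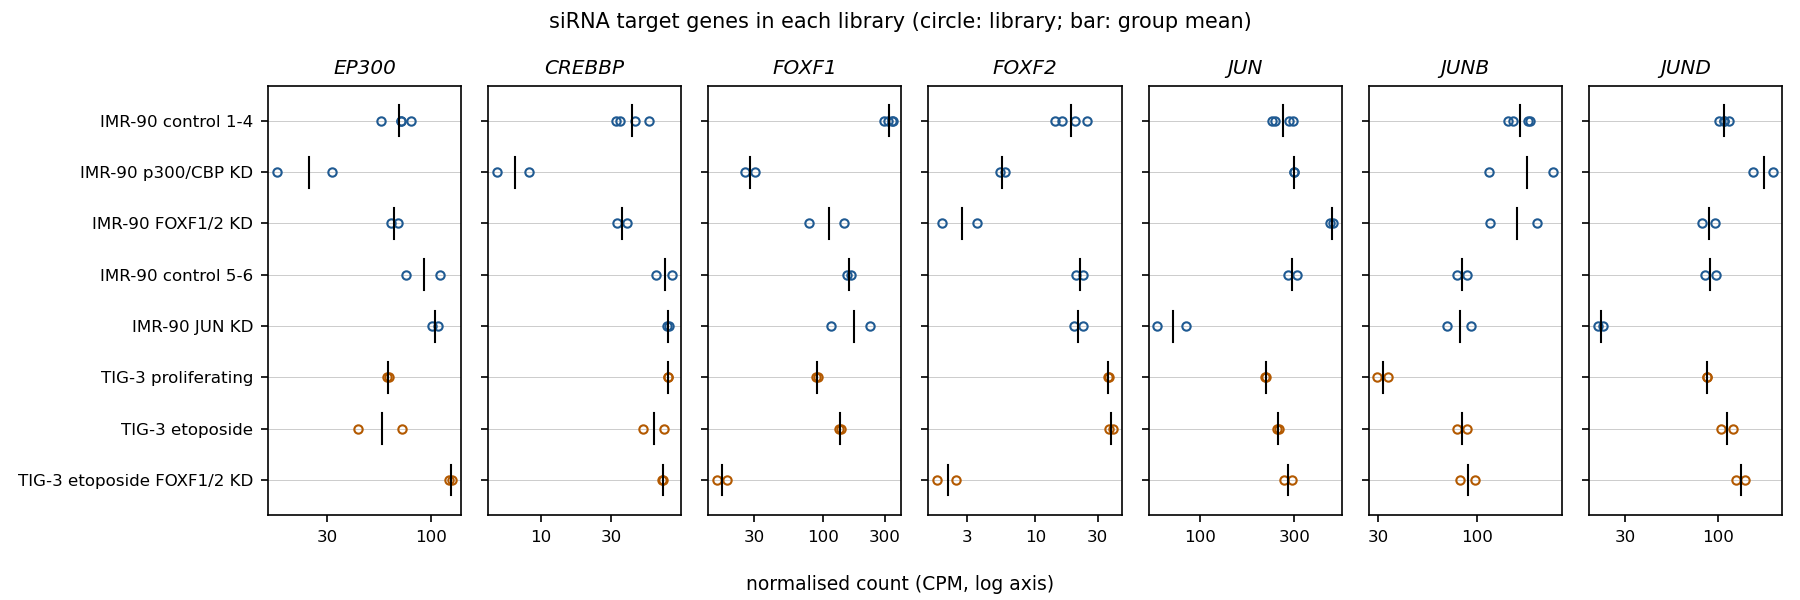
Normalised counts (CPM, log axis) of the 7 siRNA target genes, with a circle per library and a bar at each group mean. FOXF1 was at 323 CPM in IMR-90 controls 1 to 4, 27.9 in the p300/CBP knockdown and 112 in the FOXF1/2 knockdown, and JUNB was at 83.3 and 81.2 CPM in the JUN controls and knockdown.

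The p300/CBP knockdown asked what senescent IMR-90 cells express when both of these paralogous histone acetyltransferases are reduced. EP300 fell by 1.49 (SE 0.25, adjusted p = 0.000498), from 69.2 ± 9.84 to 24.3 ± 10.7 CPM, and CREBBP fell by 2.62 (SE 0.26, adjusted p = 1.29e-05), from 41.5 ± 10.0 to 6.65 ± 2.28 (controls n = 4, knockdown n = 2, as in all values of this comparison). FOXF1, a forkhead transcription factor of lung mesenchyme, fell by 3.51 (SE 0.31, adjusted p = 5.34e-06), from 323 ± 21.4 to 27.9 ± 3.71 CPM, and FOXF2 fell by 1.73 (SE 0.26, adjusted p = 0.000262). The genes for the inflammatory cytokines IL1B and IL6 also fell (-4.14, SE 0.96, and -4.40, SE 0.95), and the collagenase gene MMP1 fell by 7.38 (SE 0.89), from 3029 ± 902 to 18.0 ± 19.3 CPM. The leukocyte adhesion gene ICAM1 rose by 4.50 (SE 0.28, adjusted p = 3.9e-07), from 472 ± 85.5 to 10548 ± 569 CPM, and the laminin-binding integrin gene ITGA7 rose by 7.27 (SE 0.26), from 0.845 ± 0.440 to 129 ± 3.62 CPM.

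Other genes among the most raised were the proteoglycan gene SDC4 (5.35, SE 0.20), the apolipoprotein gene APOE (5.95, SE 0.48) and the actin crosslinker gene FLNC (4.40, SE 0.39). Genes among the most lowered included the cystatin gene CST1 (-9.54, SE 1.23) and the cadherin gene CDH6 (-8.39, SE 0.66). CHRM2, a muscarinic receptor gene, was represented by 1 count over the knockdown libraries against 1349 in the controls, a ratio of 807 after scaling (95% counting interval 145 to 31909). Of 17 tested cytokines and chemokines of the senescence-associated secretory phenotype (SASP), 11 fell, 1 rose and 5 did not pass; adjusted over the list alone the counts were 11 and 1. CXCL1, a neutrophil chemokine gene, fell by 2.72 (SE 0.60). The list had adjusted p = 0.00793, and adjusted p = 0.627 with an estimated correlation. Among 25 SASP proteases and growth factors 15 fell and 4 rose (16 and 4 adjusted over the list alone), with the protease inhibitor gene TIMP1 at 2.12 (SE 0.27). The secreted protease list gave adjusted p = 0.000295, and adjusted p = 0.617 with an estimated correlation. ICAM1 belongs to a list of NF-kB targets of which 8 of 18 rose and 1 fell without the list passing (adjusted p = 0.128).

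Matrix genes were the list with the lowest p in this knockdown: 18 of 23 fell and 1 rose (18 and 1 adjusted over the list alone), with a median of -3.36 (adjusted p = 5.93e-07, and adjusted p = 0.381 with an estimated correlation). POSTN, which encodes the matricellular protein periostin, went from 394 ± 26.0 to 5.44 ± 2.30 CPM, and the proteoglycan gene BGN fell by 6.07 (SE 0.53). TGF-beta response genes fell in 9 of 16 cases with none higher (9 and 0 adjusted over the list alone), TGFBI going from 2939 ± 261 to 57.1 ± 15.9 CPM. The TGF-beta list gave adjusted p = 0.000295, and adjusted p = 0.252 with an estimated correlation. RAS and MAPK output genes fell in 13 of 19 cases and rose in 1 (13 and 1 adjusted over the list alone); CCND1, the cyclin D1 gene, fell by 3.62 (SE 0.20). The RAS and MAPK list gave adjusted p = 0.000504, and adjusted p = 0.381 with an estimated correlation. In the list of lung mesenchyme regulators 11 of 18 fell and 4 rose (11 and 4 adjusted over the list alone), with TBX2 at -3.71 (SE 0.24) and FENDRR, a long noncoding RNA transcribed next to FOXF1, at -6.08 (SE 0.50). The lung mesenchyme list gave adjusted p = 0.0166, and adjusted p = 0.252 with an estimated correlation. Of 14 contractile genes 8 fell and 1 rose (8 and 1 adjusted over the list alone), among them ACTG2, a smooth muscle actin gene (-2.94, SE 0.63). The contractile list gave adjusted p = 0.0393, and adjusted p = 0.617 with an estimated correlation. Neither cell cycle list passed: 8 of 23 S phase genes fell and 2 rose (8 and 3 adjusted over the list alone; adjusted p = 0.185), with MCM7 at -1.71 (SE 0.13), and 4 of 23 G2 and mitosis genes fell and 1 rose (0 and 0 adjusted over the list alone; adjusted p = 0.323).

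In all, 6578 of 14163 genes changed under p300/CBP knockdown, 3299 higher and 3279 lower. Scaling by total counts alone moved the median of all genes by 0.28 and the split to 5078 higher and 2125 lower, so the directions here are relative to the TMM scaling. Without p300/CBP knockdown 1, IL1B was at -6.77 and IL6 at -7.95, and without knockdown 2 the SASP cytokine list lost its call (median -1.88, adjusted p = 0.133). The contractile list (median -0.52) lost it without knockdown 1 (adjusted p = 0.0539), knockdown 2 (0.0585) or control 3 (0.052), and its median was -0.24 with total counts alone. Leaving out 1 library took the lower members down to 6 SASP cytokines (without knockdown 2), 5 contractile genes and 0 G2 and mitosis genes (without knockdown 1), and the higher NF-kB targets to 5 (without control 1).

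The FOXF1/2 knockdown asked the same of these forkhead factors in senescent IMR-90 cells. FOXF1 fell by 1.54 (SE 0.28, adjusted p = 0.00397), from 323 ± 21.4 to 112 ± 46.7 CPM, and FOXF2 fell by 2.78 (SE 0.29, adjusted p = 0.000189), from 18.7 ± 4.65 to 2.75 ± 1.16 (controls n = 4, knockdown n = 2, as below). The monocyte chemokine genes CCL2 and CCL7 rose by 4.85 (SE 0.22) and 7.70 (SE 0.47), CCL2 from 2.18 ± 0.664 to 63.7 ± 8.85 CPM. CCL7 had 7 counts over controls 1 to 4, so the size of its rise rests on few counts. WNT16, a secreted WNT ligand gene, fell by 4.11 (SE 0.53, adjusted p = 0.000617), and the cation channel gene TRPA1 fell by 3.96 (SE 0.63, adjusted p = 0.00199), from 1203 ± 276 to 78.0 ± 49.1 CPM. The urokinase gene PLAU fell by 2.07 (SE 0.30), from 6409 ± 865 to 1539 ± 474 CPM.

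SGCD, a sarcoglycan gene (3.63, SE 0.29), NETO2 (3.61, SE 0.23), the lysyl oxidase gene LOXL4 (3.52, SE 0.33) and the proteoglycan gene SDC1 (3.32, SE 0.31) were among the most raised. COMP, a cartilage matrix gene, had 35 counts against 2 in the controls, a ratio of 34.1 (95% counting interval 8.76 to 293). Of 21 interferon-stimulated genes 9 fell and none rose (11 and 0 adjusted over the list alone); the chemokine gene CXCL10 fell by 3.92 (SE 0.53), from 19.0 ± 6.45 to 1.26 ± 0.424 CPM. The interferon list gave adjusted p = 7.47e-06, and adjusted p = 0.511 with an estimated correlation. Antigen presentation genes fell in 8 of 19 cases with none higher (10 and 0 adjusted over the list alone), among them ERAP2, a peptidase that trims antigens (-1.39, SE 0.17). The antigen presentation list gave adjusted p = 7.47e-06, and adjusted p = 0.127 with an estimated correlation. RAS and MAPK output genes fell in 9 of 19 cases and YAP and TEAD targets in 6 of 16, with none higher (12 and 8 lower adjusted over each list alone). The former had adjusted p = 1.39e-05, and adjusted p = 0.511 with an estimated correlation; the latter had adjusted p = 0.00175, and adjusted p = 0.584 with an estimated correlation.

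Neither SASP list passed in this knockdown. Of 17 cytokines and chemokines 6 fell and 2 rose (7 and 3 adjusted over the list alone; adjusted p = 0.456), the 2 higher being CCL2 and CCL7, while IL1B (-0.80, adjusted p = 0.538) and CXCL8 (-1.16, adjusted p = 0.368) did not pass. Of 25 proteases and growth factors 8 fell and 6 rose (9 and 6 adjusted over the list alone; adjusted p = 0.43), TIMP2 by 1.02 (SE 0.15) and IGFBP2, a binding protein of insulin-like growth factors, by 2.69 (SE 0.33). The G2 and mitosis list passed (adjusted p = 0.00492, and adjusted p = 0.894 with an estimated correlation) with a median of -1.29, although 1 of its 23 genes fell on its own and none did adjusted over the list alone. Of 23 S phase genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; adjusted p = 0.865).

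In all, 2276 genes changed, 1104 higher and 1172 lower. The count was 1151 without FOXF1/2 knockdown 1 and 464 without knockdown 2, with the remaining knockdown library assumed to vary like the other groups; it was 1129 with no term for the label sets, 793 and 889 with controls 1 and 2 or 3 and 4 alone, and 3820 with only the 2 groups compared. Without knockdown 2 no SASP cytokine, RAS and MAPK or YAP and TEAD gene was called lower, nor any S phase gene higher, while 2 SASP proteases, 2 interferon-stimulated and 1 antigen presentation gene were called lower. FOXF1 was then at -1.15 (adjusted p = 0.07), and at -1.27 (adjusted p = 0.0771) with no term for the label sets, a setting that also ended the calls of the 6 lower SASP cytokines, as controls 1 and 2 only did. Without control 1, 3 SASP proteases and growth factors were higher, and without knockdown 1 the G2 and mitosis list was at adjusted p = 0.0568.

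The JUN knockdown was described with controls 5 and 6 and asked about AP-1, the transcription factor that JUN proteins form. JUN fell by 2.01 (SE 0.19, adjusted p = 1.37e-05), from 294 ± 21.9 to 73.2 ± 17.3 CPM, and JUND fell by 2.05 (SE 0.15, adjusted p = 3.37e-06), from 90.2 ± 9.36 to 21.8 ± 1.13 (n = 2 each, as below), while JUNB was at 83.3 ± 7.24 and 81.2 ± 16.8 CPM (-0.04, SE 0.33, adjusted p = 0.937). Genes of the contractile cytoskeleton rose: ACTA2, the smooth muscle alpha actin gene, by 4.39 (SE 0.31, adjusted p = 2.63e-06), from 98.3 ± 44.6 to 2070 ± 87.6 CPM. Matrix genes rose too, with BGN at 4.78 (SE 0.47) and ELN, the elastin gene, at 8.18 (SE 0.53). IL1B fell by 6.83 (SE 1.14, adjusted p = 0.000749), from 2393 ± 323 to 21.2 ± 22.7 CPM, and MMP1 fell by 5.76 (SE 0.84), from 7127 ± 1015 to 133 ± 101 CPM.

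Also among the most raised were the sulfatase gene SULF1 (8.23, SE 0.33), the Notch effector gene HEYL (9.63, SE 0.80) and ANKRD1, a known YAP target (7.41, SE 0.45). COMP was 1736-fold higher (95% counting interval 594 to 8420; 3 counts in the controls). The colony-stimulating factor gene CSF3 fell by 7.75 (SE 1.36) and the thrombomodulin gene THBD fell by 6.78 (SE 0.73). Of 23 matrix genes 17 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 2.74 (adjusted p = 1.69e-06, and adjusted p = 0.527 with an estimated correlation). COL1A1, a matrix list member chosen after its values were seen, took 6.40% and 2.66% of all counts in JUN knockdown 1 and 2. Of 14 contractile genes 12 rose and none fell (12 and 1 adjusted over the list alone). The contractile list gave adjusted p = 1.4e-06, and adjusted p = 0.36 with an estimated correlation. YAP and TEAD targets rose in 11 of 16 cases and fell in 1 (11 and 1 adjusted over the list alone), among them TGFB2 (4.80, SE 0.38). The YAP and TEAD list gave adjusted p = 0.000136, and adjusted p = 0.485 with an estimated correlation. Lung mesenchyme regulators rose in 14 of 18 cases with none lower (14 and 0 adjusted over the list alone), HHIP, a Hedgehog-binding protein gene, by 4.84 (SE 0.54). The lung mesenchyme list gave adjusted p = 1.67e-05, and adjusted p = 0.0657 with an estimated correlation. Control 6 stood apart in matrix genes, with a mean log2 CPM over that list of 8.16 against 9.26 to 9.55 in the other 5 controls.

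SASP cytokines fell in 8 of 17 cases and rose in 1 (9 and 1 adjusted over the list alone), and NF-kB targets fell in 8 of 18 and rose in 1 (9 and 1 adjusted over the list alone), among them the superoxide dismutase gene SOD2 (-3.34, SE 0.55). The SASP cytokine list gave adjusted p = 0.0172, and adjusted p = 0.778 with an estimated correlation. The NF-kB list gave adjusted p = 0.00685, and adjusted p = 0.527 with an estimated correlation. SASP proteases and growth factors went both ways, 12 of 25 lower and 8 higher (14 and 9 adjusted over the list alone; adjusted p = 0.307), with MMP14 at -1.55 (SE 0.25) and the binding protein genes IGFBP3 and IGFBP7 at 3.75 (SE 0.39) and 2.99 (SE 0.30). Interferon-stimulated genes fell in 7 of 21 cases and rose in 1 (7 and 1 adjusted over the list alone), and p53 targets rose in 7 of 20 with none lower (7 and 0 adjusted over the list alone), with FAS, a death receptor gene, at 1.18 (SE 0.26). The interferon list gave adjusted p = 0.0346, and adjusted p = 0.671 with an estimated correlation. The p53 list gave adjusted p = 0.0158, and adjusted p = 0.527 with an estimated correlation. Of 23 S phase genes 9 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.126). G2 and mitosis genes, of which 7 of 23 fell (6 adjusted over the list alone), did not pass as a list (adjusted p = 0.0509), and their mean log2 CPM was 2.55 in control 5 and -0.04 in control 6. Without control 6 that list had a median of -2.46 (adjusted p = 9.88e-08) with 17 genes lower, and without control 5 a median of 0.28 with 0 genes lower. Without control 5 the lower S phase genes were 5, and TK1, which did not pass with both controls (-0.58, adjusted p = 0.557), was at 1.77 (adjusted p = 0.0229).

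In all, 5166 genes changed under JUN knockdown, 2645 higher and 2521 lower; total counts alone moved the median of all genes by -0.29 and the split to 1752 higher and 4237 lower. With only the 2 groups compared, which does not borrow the spread of the other IMR-90 groups, 2932 genes changed, and IL1A, CXCL2, MMP3 and MKI67 were among those that lost their calls (adjusted p = 0.072, 0.0632, 0.0823 and 0.199). The SASP cytokine median of -1.38 was -3.68 without JUN knockdown 2, and the list lost its call without control 6 (adjusted p = 0.0529), JUN knockdown 1 (0.125) or with total counts alone (0.142); without JUN knockdown 1 the NF-kB median of -0.69 was -0.39. The interferon list lost its call without control 5 (-0.74, adjusted p = 0.303), with total counts alone (0.142) or with the length trend removed (0.0582). The p53 list, at 0.43, lost it without control 5 (0.25, adjusted p = 0.215), JUN knockdown 2 (0.21, adjusted p = 0.114) or with total counts alone (0.16, adjusted p = 0.0568), and was at 0.70 without JUN knockdown 1. Its higher members were 3 without control 5, and without control 6 the lower SASP cytokines and the higher SASP proteases were 5 each.

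Etoposide senescence in TIG-3 was compared with proliferating cells (n = 2 each, as below). The complement gene C3 rose by 7.38 (SE 0.21, adjusted p = 3.67e-06), from 1.96 ± 0.735 to 320 ± 33.3 CPM, and the chemokine gene CXCL8 rose by 4.97 (SE 0.34), from 2.20 ± 0.569 to 69.5 ± 30.7 CPM. The stromelysin gene MMP3 rose by 5.31 (SE 0.19), the epithelial transcription factor gene EHF by 4.93 (SE 0.25) and the EGF receptor ligand gene AREG by 4.00 (SE 0.14). Among proliferation genes, MKI67 fell by 2.82 (SE 0.43, adjusted p = 0.00232). TOP2A, a topoisomerase gene, fell by 2.49 (SE 0.15), from 90.8 ± 7.56 to 16.1 ± 1.46 CPM. The oxytocin receptor gene OXTR fell by 3.01 (SE 0.096) and the collagen gene COL11A1 fell by 2.84 (SE 0.14), from 811 ± 16.1 to 113 ± 22.8 CPM.

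Of 17 SASP cytokines and chemokines 15 rose and none fell (15 and 0 adjusted over the list alone), with a median of 4.02 (adjusted p = 2.28e-13, and adjusted p = 0.131 with an estimated correlation). IL1B rose by 4.39 (SE 0.37), from 0.645 ± 0.119 to 13.5 ± 5.67 CPM, and IL6 by 2.31 (SE 0.27). CSF3 had 150 counts against 0 in the proliferating cells, at least 45.4-fold higher than a floor of 3 counts over the group. SASP proteases and growth factors rose in 14 of 25 cases and fell in 6 (16 and 6 adjusted over the list alone), among them STC1 (3.15, SE 0.10) and IGFBP3 (-2.45, SE 0.099). The secreted protease list gave adjusted p = 5.63e-05, and adjusted p = 0.179 with an estimated correlation. NF-kB targets rose in 14 of 18 cases and RAS and MAPK output genes in 12 of 19, with none lower (14 and 13 higher adjusted over each list alone). The former had adjusted p = 8.17e-10 and the latter adjusted p = 1.13e-07, and both had adjusted p = 0.131 with an estimated correlation; SOD2 rose by 2.40 (SE 0.19) and the MAPK phosphatase gene DUSP6 by 1.45 (SE 0.094). Of 20 p53 targets 10 rose and none fell (11 and 0 adjusted over the list alone), among them GDF15 (2.18, SE 0.11). The p53 list gave adjusted p = 2.81e-05, and adjusted p = 0.131 with an estimated correlation.

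All 25 G2 and mitosis genes fell (25 adjusted over the list alone), as did 23 of 25 S phase genes (23 adjusted over the list alone). The mitosis list gave a median of -2.20, adjusted p = 3.42e-20, and adjusted p = 0.0877 with an estimated correlation. The S phase list gave a median of -1.25, adjusted p = 2.28e-13, and adjusted p = 0.131 with an estimated correlation. PLK1, a mitotic kinase gene, fell by 2.66 (SE 0.16) and the thymidine kinase gene TK1 fell by 2.23 (SE 0.14). Matrix genes fell in 21 of 23 cases and YAP and TEAD targets in 13 of 16, with none higher (21 and 13 lower adjusted over each list alone). Matrix genes had adjusted p = 7.33e-15 and YAP and TEAD targets adjusted p = 4.85e-09, and both had adjusted p = 0.131 with an estimated correlation. Contractile genes fell in 12 of 16 cases (14 adjusted over the list alone). The contractile list gave adjusted p = 3.57e-10, and adjusted p = 0.0877 with an estimated correlation. Examples were COL5A1, a fibrillar collagen gene (-1.90, SE 0.11), ACTG2 (-1.84, SE 0.11) and ANKRD1 (-2.31, SE 0.21). Lysosome genes rose in 9 of 20 cases and fell in 2 (11 and 2 adjusted over the list alone), and genes of the unfolded protein and ATF4 response fell in 9 of 16 and rose in 3 (9 and 3 adjusted over the list alone), with the serine synthesis gene PSAT1 at -1.94 (SE 0.11). The lysosome list gave adjusted p = 0.00631, and adjusted p = 0.409 with an estimated correlation. The unfolded protein list gave adjusted p = 0.00786, and adjusted p = 0.409 with an estimated correlation. AP-1 subunit genes rose in 5 of 14 cases and fell in 2 (5 and 2 adjusted over the list alone), ATF3 by 2.27 (SE 0.13) and JUNB by 1.39 (SE 0.11). The AP-1 list gave adjusted p = 0.0427, and adjusted p = 0.179 with an estimated correlation. FOXF1 rose by 0.59 (SE 0.11, adjusted p = 0.0057), from 90.6 ± 1.62 to 136 ± 2.78 CPM, and FOXF2 did not pass (0.07, SE 0.12, adjusted p = 0.705).

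In all, 3563 of 14422 genes changed with etoposide, 1577 higher and 1986 lower. Total counts alone moved the median of all genes by 0.22 and the split to 3899 higher and 1156 lower. The medians of the p53, lysosome and unfolded protein lists moved with it from 0.34, 0.25 and -0.37 to 0.56, 0.47 and -0.15. The count was 1578 without proliferating control 1, where FOXF1 was at 0.56 (adjusted p = 0.07), and 2008 without control 2. Without control 1 the higher members were 5 in the p53, 3 in the lysosome and 3 in the AP-1 list, and the lower ones 4 in the unfolded protein list. The AP-1 list (median 0.18) lost its call without senescent control 2 (median 0.14, adjusted p = 0.101) or with total counts alone (0.40, adjusted p = 0.122).

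FOXF1/2 knockdown in etoposide-senescent TIG-3 cells asked whether these factors act alike with another line and inducer. FOXF1 fell by 3.01 (SE 0.12, adjusted p = 4.87e-06), from 136 ± 2.78 to 17.1 ± 2.18 CPM, and FOXF2 fell by 4.20 (SE 0.16, adjusted p = 4.68e-06), from 38.0 ± 1.54 to 2.13 ± 0.504 (n = 2 each, as below). TRPA1 fell by 4.88 (SE 0.16), from 188 ± 7.65 to 6.55 ± 1.34 CPM, and WNT16 fell by 4.20 (SE 0.12). The axon guidance gene SEMA3A and the BMP receptor gene ACVRL1 also fell (-3.64, SE 0.11, and -3.59, SE 0.12). HHIP rose by 3.65 (SE 0.18), from 3.82 ± 0.285 to 48.5 ± 7.19 CPM, and the thrombospondin gene THBS2 rose by 2.38 (SE 0.093). EP300 rose by 1.13 (SE 0.20, adjusted p = 0.00405), from 57.0 ± 20.2 to 126 ± 2.91 CPM.

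Of 17 SASP cytokines and chemokines 13 fell and 1 rose (14 and 1 adjusted over the list alone), with a median of -1.69 (adjusted p = 0.000117, and adjusted p = 0.527 with an estimated correlation). CXCL8 fell by 2.79 (SE 0.29), from 69.5 ± 30.7 to 10.1 ± 1.11 CPM, and CXCL1 (-3.35, SE 0.35), IL1B (-1.69, SE 0.29) and IL6 (-1.59, SE 0.26) fell too. SASP proteases and growth factors fell in 15 of 25 cases and rose in 5 (16 and 5 adjusted over the list alone); PLAU fell by 2.65 (SE 0.093), from 1856 ± 101 to 300.1 ± 17.3 CPM. The secreted protease list gave adjusted p = 0.000728, and adjusted p = 0.527 with an estimated correlation. Matrix genes rose in 18 of 23 cases and fell in 3 (19 and 3 adjusted over the list alone), with a median of 0.82 (adjusted p = 9.01e-07, and adjusted p = 0.527 with an estimated correlation); COL5A3, a collagen gene, rose by 2.47 (SE 0.12) and the proteoglycan gene LUM fell by 1.70 (SE 0.14). Of 19 interferon-stimulated genes 13 fell and none rose (18 and 0 adjusted over the list alone), among them CXCL10 (-5.21, SE 0.63). The interferon list gave adjusted p = 5.05e-05, and adjusted p = 0.527 with an estimated correlation. NF-kB targets fell in 8 of 18 cases with none higher (9 lower and 1 higher adjusted over the list alone), among them PTGS2, the cyclooxygenase gene (-2.58, SE 0.20). The NF-kB list gave adjusted p = 0.00417, and adjusted p = 0.527 with an estimated correlation.

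Of 25 G2 and mitosis genes 22 fell and none rose (24 and 0 adjusted over the list alone), with a median of -1.59 (adjusted p = 1.04e-11, and adjusted p = 0.379 with an estimated correlation), among them BIRC5, the survivin gene (-2.54, SE 0.18). S phase genes fell in 12 of 25 cases and rose in 1 (12 and 1 adjusted over the list alone); RRM2, a ribonucleotide reductase gene, fell by 2.98 (SE 0.17). The S phase list gave adjusted p = 0.000416, and adjusted p = 0.527 with an estimated correlation. In all, 4394 genes changed, 2026 higher and 2368 lower, and total counts alone moved the median of all genes by -0.14 and the split to 1316 higher and 3626 lower. The count was 2400 without TIG-3 FOXF1/2 knockdown 1, where the S phase median was -0.24 in place of -0.43, and 2788 without knockdown 2. Without senescent control 1 the NF-kB list lost its call (median -0.28 in place of -0.42, adjusted p = 0.0599), and the interferon median of -1.68 was -2.64 without that control and -0.77 without control 2. Lower interferon-stimulated genes were 5 without knockdown 2, and lower NF-kB targets 5 without knockdown 1.

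**Figure D2:**
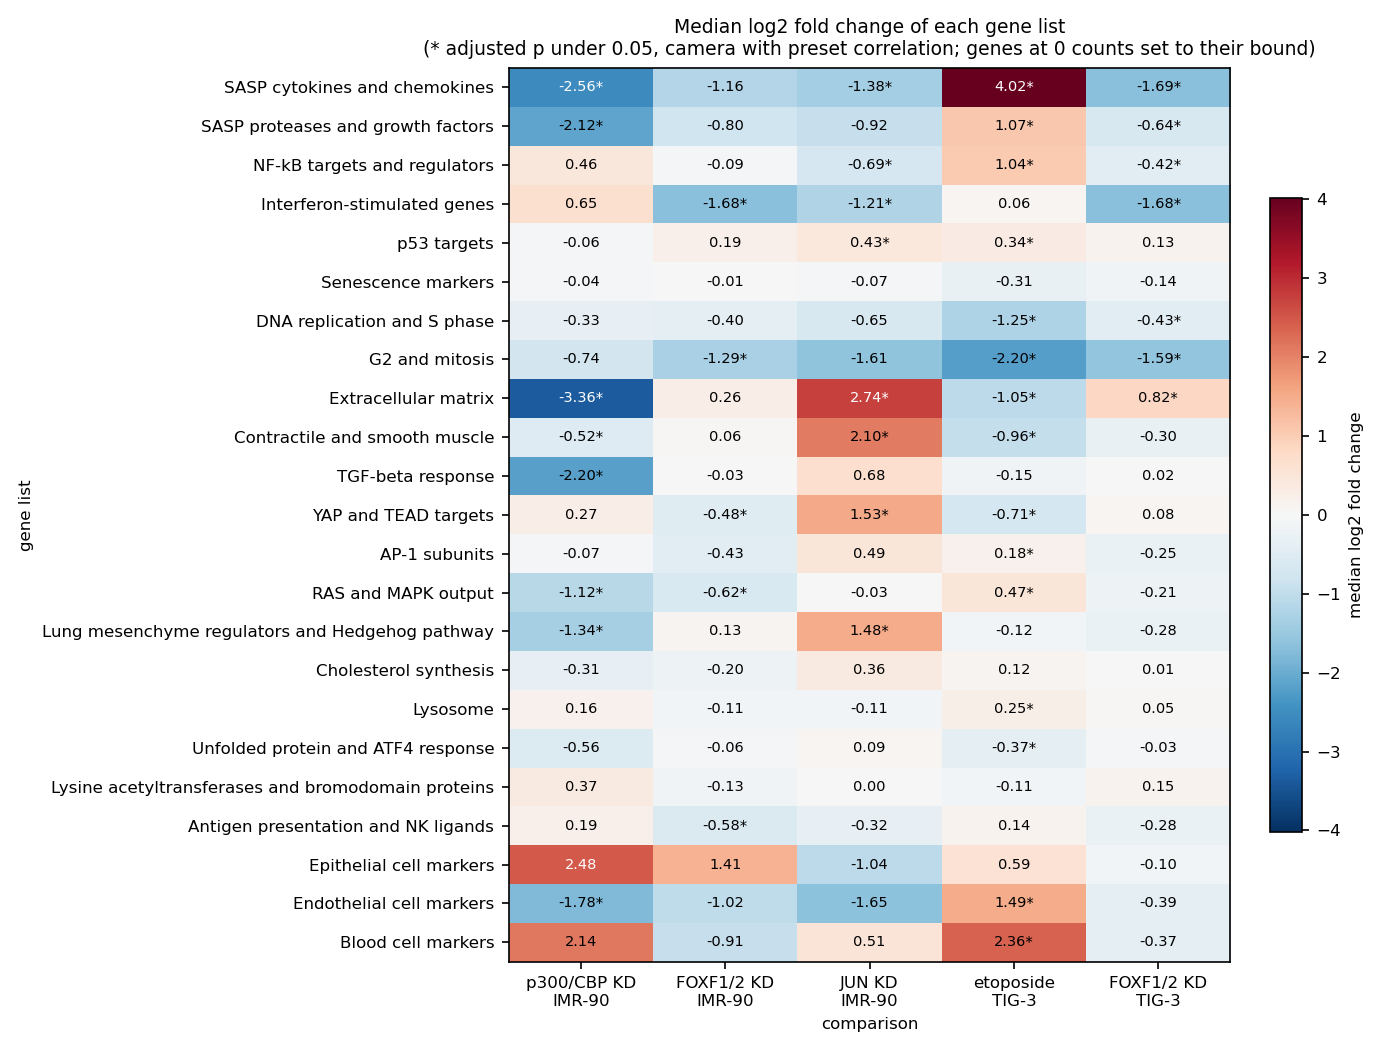
Median log2 fold change of each gene list (vertical axis) in the 5 comparisons (horizontal axis), with colour for the median and an asterisk for an adjusted p under 0.05 with the preset correlation. The SASP cytokine list was at 4.02 with etoposide and at -1.69 with FOXF1/2 knockdown in TIG-3, and the matrix list was at -3.36 with p300/CBP and 2.74 with JUN knockdown.

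The FOXF1/2 knockdowns of the lines were compared in a fit to all 18 libraries, in which line and inducer of senescence cannot be told apart. A positive difference means a higher log2 fold change in IMR-90 than in TIG-3. CYP26B1, a retinoic acid hydroxylase gene, fell by 3.71 in IMR-90 and rose by 2.26 in TIG-3 (difference -6.01, SE 0.80, adjusted p = 0.000634); its IMR-90 call ended without FOXF1/2 knockdown 2 (adjusted p = 0.0629) or with no term for the label sets (adjusted p = 0.0714). ID2, an inhibitor of basic helix-loop-helix factors, rose by 2.93 in IMR-90 and fell by 1.68 in TIG-3 (difference 4.58, SE 0.40, adjusted p = 2.28e-05). The GABA receptor gene GABRA2 fell by 4.97 in TIG-3 and did not pass in IMR-90 (-0.47, adjusted p = 0.171; difference 4.46, SE 0.37). LYPD1 (4.04, SE 0.58), OLFML3 (3.89, SE 0.59) and ADAMTSL1 (3.78, SE 0.54) were the next highest, and ENPP1 (-4.04, SE 0.59), SERPINB7 (-3.39, SE 0.56), PRSS23 (-3.37, SE 0.34) and SLC4A7 (-3.23, SE 0.41) the next lowest. The knockdown itself differed: FOXF1 was higher by 1.44 (SE 0.35, adjusted p = 0.0237) and FOXF2 by 1.37 (SE 0.38, adjusted p = 0.0408) in the IMR-90 comparison, that is, less reduced.

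Of 25 S phase genes 5 were higher in the difference and none lower (9 and 1 adjusted over the list alone), with a median of 0.75 (adjusted p = 0.00291, and adjusted p = 0.357 with an estimated correlation). YAP and TEAD targets were lower in 3 of 16 cases, RAS and MAPK output genes in 3 of 19 and antigen presentation genes in 5 of 19, with none higher (10, 4 and 6 lower adjusted over each list alone). Their medians were -0.78 (adjusted p = 0.0017, and adjusted p = 0.357 with an estimated correlation), -0.38 (adjusted p = 0.00587, and adjusted p = 0.616 with an estimated correlation) and -0.35 (adjusted p = 0.00587, and adjusted p = 0.357 with an estimated correlation). In all, 1044 of 14965 genes differed, 498 higher and 546 lower, and total counts alone moved the median by 0.21 and the split to 878 and 266. The count was 400 with no term for the label sets and 2021 with only the 4 groups compared. Leaving out a library of either line's FOXF1/2 knockdown or a TIG-3 senescent control left 374 to 599 genes: 549 and 481 without IMR-90 knockdown 1 and 2, 418 and 599 without TIG-3 senescent control 1 and 2, and 374 and 461 without TIG-3 knockdown 1 and 2. The differences of FOXF1 and FOXF2 lost their calls without IMR-90 knockdown 1 (0.94, adjusted p = 0.15, and 0.88, adjusted p = 0.29) and without either TIG-3 senescent control or either TIG-3 knockdown, with values up to 1.58 and 1.63. The FOXF2 difference also lost it without controls 1, 3 or 4 (1.26 to 1.41). With no term for the label sets the calls of LYPD1 (3.15), ADAMTSL1 (2.39), SLC4A7 (-2.81), FOXF1 (1.71, adjusted p = 0.101) and FOXF2 (adjusted p = 0.0839) ended. The RAS and MAPK median was -0.58 without IMR-90 knockdown 1 and -0.20 without knockdown 2 (adjusted p = 0.142), the antigen presentation median was -0.20 without TIG-3 knockdown 1, and these were -0.17 and -0.14 with total counts alone. Members called went down to 0 S phase and 1 RAS and MAPK gene without IMR-90 knockdown 2, and to 0 YAP and TEAD and 2 antigen presentation genes without IMR-90 knockdown 1.

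**Figure D3:**
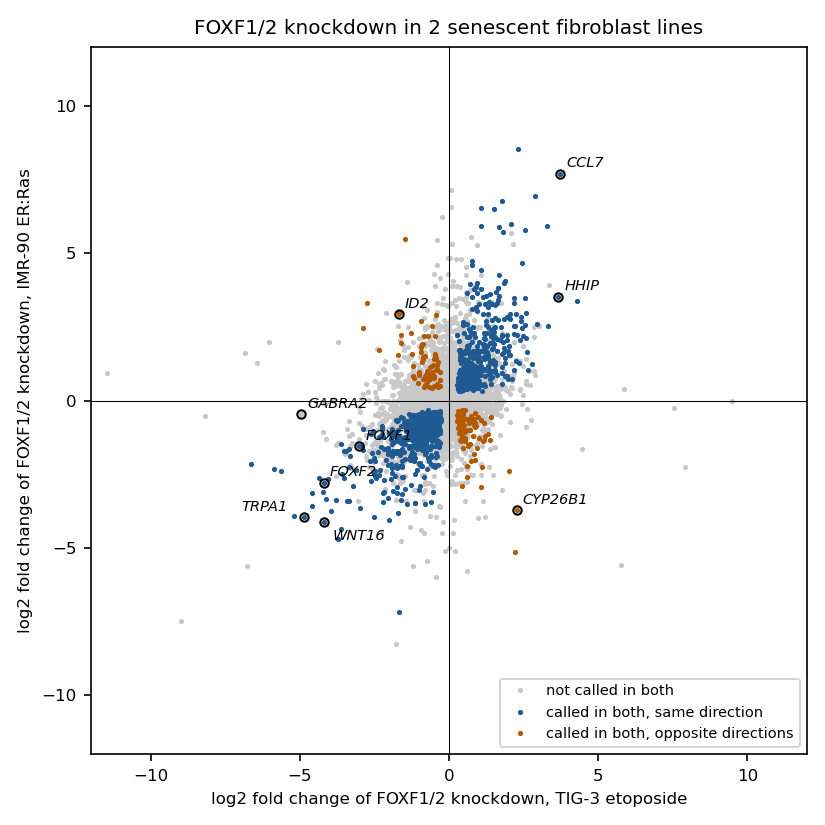
Log2 fold change of each gene under FOXF1/2 knockdown in TIG-3 (horizontal axis) and IMR-90 (vertical axis), coloured by whether the gene passed in both lines with the same or opposite directions. TRPA1 was at -4.88 and -3.96 and WNT16 at -4.20 and -4.11 in TIG-3 and IMR-90, while CYP26B1 was at 2.26 and -3.71.

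Overlaps between comparisons were set against the number that independent calls would share. FOXF1/2 knockdown raised 452 genes in both lines (156 with independent calls) and lowered 569 (192), among them TRPA1 and WNT16, and 145 went opposite ways. The libraries are separate, and across 13670 genes, which are not independent replicates, Pearson's r was 0.399. The 1021 genes changed the same way were 629 without IMR-90 FOXF1/2 knockdown 1 and 266 without knockdown 2. In IMR-90 the p300/CBP and FOXF1/2 knockdowns were both set against controls 1 to 4. Chance error in these controls thus moves both changes the same way. Both lowered 557 genes (271 with independent calls), including FOXF1, FOXF2, PLAU and TRPA1, and both raised 310 (257). Opposite calls were 332 genes lower under p300/CBP and higher under FOXF1/2 knockdown (256), and 249 the reverse (273). Unchanged groups simulated against the same controls had a mean covariance of 0.0666 against 0.318 observed, and a mean Pearson's r of 0.336 against 0.233. They shared 0 genes in 20 simulations, but with no change almost no gene is called. That number therefore cannot show how much the controls add to the overlap. With different controls for the knockdowns, 258 and 240 genes were lower in both (81.0 and 74.0 with independent calls) and 90 and 85 higher (69.0 and 60.9), with covariances of 0.254 and 0.271. Genes lower under p300/CBP and higher under FOXF1/2 knockdown were then 133 and 108 (74.6 and 64.1), and the reverse 70 and 60 (75.0 and 70.4). The 557 genes were 338 without FOXF1/2 knockdown 1 and 106 without knockdown 2.

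The JUN and p300/CBP knockdowns had no controls in common, and both raised 797 genes (616 with independent calls) and lowered 1020 (584), with 349 higher under p300/CBP and lower under JUN knockdown (587) and 689 the reverse (612). MMP1 and IL1B fell in both, while BGN fell in p300/CBP and rose in JUN knockdown. JUN and FOXF1/2 knockdown both raised 338 genes (206) and lowered 298 (209), while 299 and 268 went opposite ways (197 and 219). JUN itself fell in its own knockdown and was called higher under FOXF1/2 knockdown in IMR-90. That call ended without FOXF1/2 knockdown 2, where JUN was at 0.84. The 636 genes changed the same way were 326 without FOXF1/2 knockdown 1 and 191 without knockdown 2. In TIG-3 the etoposide and FOXF1/2 comparisons share the senescent controls, with opposite sign, so chance error in them moves the changes apart and part of the excess may come from it. Of the genes called in both, 438 were higher with etoposide and lower with knockdown (259 with independent calls), among them CXCL8, and 541 the reverse (279), among them COL5A1. Simulations with no change gave 0.200 and 0.350 such genes on average, which cannot size the excess, since almost no gene is called in them. Their covariance over all genes was -0.0531 against -0.0518 observed. These simulations hold no error shared between groups by replicate number. The 979 genes with opposite calls were 528 and 605 without proliferating control 1 and 2, 1508 without senescent control 2 and 628 without FOXF1/2 knockdown 1.

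Genes that etoposide raised or lowered at least 2-fold in TIG-3 were then followed in IMR-90, whose libraries are separate. Over all genes tested, 46.4% changed under p300/CBP, 16.1% under FOXF1/2 and 36.5% under JUN knockdown in IMR-90. Of 596 raised genes tested, 261 fell and 111 rose under p300/CBP knockdown (263 and 122 adjusted over the list alone), with a median of -0.88 (adjusted p = 0.000139, and adjusted p = 0.778 with an estimated correlation), and MMP1 was among those that fell. The same genes had a median of 0.00 under FOXF1/2 knockdown, with 102 higher and 99 lower (122 and 112 adjusted over the list alone, list adjusted p = 0.888). These calls went both ways, so the median does not show that the genes stayed unchanged. Under JUN knockdown the median was -0.43, with 139 higher and 186 lower (150 and 205 adjusted over the list alone, list adjusted p = 0.168). Of 518 lowered genes tested, 204 rose and 80 fell under JUN knockdown (214 and 94 adjusted over the list alone; median 0.45, adjusted p = 0.000101, and adjusted p = 0.778 with an estimated correlation), ELN and ANKRD1 among the higher. Under p300/CBP and FOXF1/2 knockdown the lowered genes did not pass, with medians of -0.20 and -0.22 (adjusted p = 0.406 for each). For genes that etoposide lowered by at least 2 (log2), the call under JUN knockdown ended and the median turned (-1.29, 21 higher and 20 lower of 90, adjusted p = 0.848, with the test pointing up). Those genes had a median of -0.84 under p300/CBP knockdown (adjusted p = 0.148) and passed under FOXF1/2 knockdown (-1.03, 2 higher and 4 lower, adjusted p = 0.0022, and adjusted p = 0.986 with an estimated correlation). The genes raised by at least 2 had a median of -1.58 under p300/CBP knockdown. The JUN median of 0.45 was 1.02 without control 5, 0.29 without JUN knockdown 1 and 0.16 with total counts alone. With total counts alone the p300/CBP median of the lowered genes turned to 0.05, and without JUN knockdown 2 the raised genes had a median of -0.78 under JUN knockdown.

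Markers of other cell types were read in every library, as these fibroblasts could hold traces of epithelial, endothelial or blood cells. Endothelial markers summed to 43.9 to 71.6 CPM in the 6 IMR-90 controls and 4.21 to 8.00 in the p300/CBP knockdown, in which 4 of 7 fell (4 adjusted over the list alone; median -3.93, or -1.78 with KDR, which had 0 counts, at its bound; adjusted p = 0.0166, and adjusted p = 0.252 with an estimated correlation). TEK, an angiopoietin receptor gene, fell by 5.55 (SE 0.45). In the JUN knockdown the endothelial sums were higher, at 77.7 and 73.7 CPM (56.1 and 43.9 in controls 5 and 6). There 2 of 7 markers rose and 2 fell, and the list did not pass (adjusted p = 0.587). TEK was the highest endothelial marker in that knockdown (66.3 and 64.3 CPM) and in all TIG-3 libraries, so these sums rest largely on this gene. Under FOXF1/2 knockdown the endothelial sums were 28.8 and 31.7 CPM in IMR-90 (45.4 to 71.6 in controls 1 to 4) and 21.4 and 22.2 in TIG-3 (45.3 and 52.4 in the senescent controls). TEK fell by 3.13 (SE 0.36) and 1.74 (SE 0.12) there, while the list did not pass in either line (in IMR-90 1 of 7 rose and 1 fell, as they did adjusted over the list alone, adjusted p = 0.456; in TIG-3 2 of 7 fell, 2 adjusted over the list alone and 1 without senescent control 2, adjusted p = 0.351). In TIG-3 the sums were 31.7 to 32.5 CPM in proliferating and 45.3 to 52.4 in etoposide-treated cells, where 6 of 7 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.00208, and adjusted p = 0.131 with an estimated correlation); ERG was at least 8.77-fold and PECAM1 at least 7.87-fold higher than a floor of 3 counts over the proliferating libraries. All 3 tested blood markers rose with etoposide, and 3 did adjusted over the list alone (median 2.36, adjusted p = 0.00256, and adjusted p = 0.131 with an estimated correlation). PTPRC rose at least 9.68-fold. The median was 4.09 or 4.10 without proliferating control 1 or 2 and 4.66 without senescent control 2. More genes were detected in the etoposide-treated controls (18341 and 18456) than in proliferating cells (16444 and 16514). Whether the rises of ERG, PECAM1 and PTPRC from 0 counts are part of a wider gain of low-level transcripts was not tested. Epithelial markers summed to 3.16 and 4.73 CPM in the p300/CBP knockdown and 0.393 to 1.04 in its controls, and 2 of 3 tested rose there (2 adjusted over the list alone; 1 without knockdown 1) without the list passing (adjusted p = 0.112). EPCAM had 69 counts against 3, a ratio of 38.4 (95% counting interval 12.6 to 191). Blood markers summed to 119 and 127 CPM in that knockdown and 54.5 to 86.3 in its controls, and 2 of 3 rose (2 adjusted over the list alone; 1 without control 2; list adjusted p = 0.185), CD68 by 0.82 (SE 0.27).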

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

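All tests of explanations in this part were chosen only after the results were seen, as were the alternatives of total-count scaling and removal of the length trend; the test of the difference between the lines was planned.

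Among 184 values checked in the 6 IMR-90 controls, 24 had a lowest or highest library set apart from the other 5 by more than Dixon's criterion allows. Chance gives about 5% only if the 6 controls are alike. Controls 5 and 6, where most flags fell, are a separate label set that differed from controls 1 to 4 in 2594 of 14163 genes. Many values were also of genes named from comparisons with these controls, so that rate does not apply here. Control 5 was high in cycling genes, with MKI67 at 18.7 CPM (others 0.830 to 6.73), KIF20A at 4.36 (0.237 to 1.26), ASPM at 7.17 (0.593 to 2.45), MCM10 at 1.75 (0.194 to 0.504) and CCNE2 at 1.196 (0.306 to 0.593). It was also high in FLNC at 912 CPM (333 to 475), MEDAG at 22.6 (2.66 to 8.47), C3 at 180.1 (76.6 to 114) and OLFML3 at 4.95 (0.978 to 2.13). Control 6 was low in matrix genes, with a mean log2 CPM of 8.16 over that list (others 9.26 to 9.55) and COL5A3 at 15.0 CPM (71.8 to 98.8). It was high in the inflammatory genes CSF3 at 354 (132 to 206), CCL20 at 204 (33.3 to 67.5), PTGS2 at 461 (82.9 to 208) and CEBPB at 332 (139 to 185). Also high there were PSAT1 at 423 (34.2 to 171), LUM at 108 (25.7 to 41.6), NETO2 at 38.0 (9.66 to 20.2), RELN at 14.4 (2.44 to 6.36), ID2 at 5.89 (1.34 to 2.35) and GABRA2 at 40.0 (30.4 to 33.0). In control 3 the most abundant gene took 1.37% of counts (1.04% to 1.11% in the others) and APOE was at 3.82 CPM (1.27 to 2.20), and in control 1 ITGA7 was at 1.47 (0.505 to 0.843).

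Matrix and contractile genes were higher under JUN knockdown, which was set against controls 5 and 6. Control 6, with its low matrix genes, did not account for this as a whole: without it the matrix list kept a median of 2.04 (adjusted p = 9.76e-06) and the contractile list one of 1.65, although with an estimated correlation and all libraries neither passed (adjusted p = 0.527 and adjusted p = 0.36). With total counts in place of TMM the matrix median was 2.42, so the choice between these scalings did not account for it either. That setting moved the median of all genes by -0.29 and leaves the abundant genes in. It therefore does not test whether a few genes taking many counts matter. The HRAS log2 fold change had a lower 95% limit of -0.30. Counts per gene symbol do not tell a RAS transgene from the cells' own HRAS, so less transgene in the knockdown stays open. An effect of the JUN knockdown itself remains a hypothesis, and the 2 control libraries may still set its size, which ranged from 2.04 to 3.38 when single libraries were left out.

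Secreted-factor and matrix genes were lower under p300/CBP knockdown, with a median of -2.79 over the 3 lists. With the length trend of each library removed it was -2.80, and with total counts alone it was -2.52, and the 3 lists kept their calls under both with the preset correlation (with an estimated correlation and TMM they had adjusted p = 0.627, 0.617 and 0.381), so neither accounts for the change. The HRAS log2 fold change had a lower 95% limit of -0.13, which for the same reason leaves less RAS transgene open. RAS and MAPK output genes fell in 13 of 19 cases and rose in 1 under this knockdown (median -1.12). That the loss of the acetyltransferases caused the change remains a hypothesis, found and tested on the same data. Effects of the siRNAs on other genes were not tested.

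The response to FOXF1/2 knockdown differed between the lines for 1044 genes by the test of the difference itself, including CYP26B1 (-6.01), ENPP1 (-4.04), SERPINB7 (-3.39), PRSS23 (-3.37), SLC4A7 (-3.23), ID2 (4.58), GABRA2 (4.46), LYPD1 (4.04), OLFML3 (3.89) and ADAMTSL1 (3.78). FOXF1 (1.44), FOXF2 (1.37) and EP300 (-1.25) differed too, though each lost its call without the label-set term (EP300 at adjusted p = 0.0714) and, for EP300, with total counts (0.115), a CPM of at least 1 (0.0517) or without 1 of 8 single libraries (up to 0.215, at -0.93 without TIG-3 senescent control 1). The S phase (0.75), YAP and TEAD (-0.78), RAS and MAPK (-0.38) and antigen presentation (-0.35) lists differed with the preset correlation, by these medians, and not with an estimated correlation (adjusted p = 0.357, 0.357, 0.616 and 0.357). A shallower knockdown in IMR-90 could make responses weaker there. Of the genes, 51.0% (526 of 1031 tested in both lines) were called in IMR-90 and moved more there, or were called in opposite directions in both lines. They were picked by the difference on the same data, which favours overestimated changes. Most IMR-90 calls also ended without FOXF1/2 knockdown 2. The share therefore argues against a shallower knockdown only as far as those calls hold. The length trend is argued against because 96.0% of the genes kept call and direction without it. For the other 505 genes a shallower knockdown and a difference between the lines cannot be told apart, since a response near 0 in IMR-90 takes either sign by chance. The line, its inducer of senescence and the label set of its libraries stay open and untested.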

How the results depend on the processing

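The alternatives of total counts alone and of removing the length trend were chosen only after the results were seen; the others were planned. Summary values were recomputed in each alternative. Of these, 303 stayed within 1.5 times for a count, or kept direction and side of the threshold for a median. Another 76 moved, a count by 1.5 times or more or a median to the other sign with no call in either setting. A further 2 changed sign with a call in at least 1 setting (reversed), 2 lost and 2 gained a call. For single genes, read by sign and call as the medians were, these numbers were 7995, 160, 5, 428 and 203. A gene that kept its call could still shift by over 1.5 times, as IL6 did under p300/CBP knockdown (-4.40, and -7.95 without knockdown 1). DESeq2 gave no adjusted p for 3 genes in each IMR-90 comparison and in the difference between the lines. The cause was not tested except where the construction of an alternative gives it (a stricter threshold or fewer libraries).

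With an absolute log2 fold change of at least 1, the calls were 3329 for p300/CBP, 1061 for FOXF1/2 in IMR-90, 2828 for JUN, 1291 for etoposide, 1338 for FOXF1/2 in TIG-3 and 682 for the difference. The overlaps were then 298 genes (lower in p300/CBP and FOXF1/2), 326 (FOXF1/2 in both lines), 329 (FOXF1/2 and JUN), 812 (p300/CBP and JUN) and 225 (opposite in etoposide and FOXF1/2 in TIG-3). With an estimated correlation, 0 lists passed in each of the 6 comparisons by camera. Genes induced by senescence in TIG-3 then missed the threshold under p300/CBP knockdown (median -0.88, adjusted p = 0.778), as did those repressed there under JUN knockdown (0.45, adjusted p = 0.778); in the other alternatives these lists were read at an unadjusted p under 0.05.

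Without the label-set term, FOXF1/2 in IMR-90 gave 1129 genes, 241 of them lower with p300/CBP too and 560 shared between the lines, and the difference gave 400. With only the 2 groups compared, FOXF1/2 in IMR-90 gave 3820 and JUN 2932, and with only the 4 groups compared the difference gave 2021 genes and 6 lists. With controls 1 and 2 alone, FOXF1/2 in IMR-90 gave 793, and the overlaps were 249 with p300/CBP, 423 between lines and 281 with JUN. With controls 3 and 4 alone these were 889, 261, 473 and 284. With separate controls for each knockdown the overlap of lower genes was 258 or 240. Genes induced in TIG-3 had a median near 0 under FOXF1/2 knockdown in IMR-90: 0.075 with controls 3 and 4, 0 with RLE, 0.0295 with no filter, 0.0018 with total counts and 0 for genes changed by at least 2 (log2) in TIG-3. With that threshold, repressed genes gained a call under FOXF1/2 knockdown (-1.03, adjusted p = 0.0022, and adjusted p = 0.986 with an estimated correlation), although 2 of 90 rose and 4 fell. Under JUN knockdown their median turned to -1.29, while the test, which did not pass, pointed up (adjusted p = 0.848). With total counts alone, which moved the median of all genes by 0.28 under p300/CBP and by -0.29 under JUN knockdown, repressed genes turned under p300/CBP knockdown (0.0484, unadjusted p = 0.0122), JUN gave 5 lists and the opposite overlap in TIG-3 was 1567.

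The samples share only a replicate number. With it as a block, etoposide gave 6029 genes, FOXF1/2 in TIG-3 6723, the opposite overlap 1955, and the difference 2808 genes and 7 lists. Differences between replicates 1 and 2 correlated across genes between the TIG-3 groups (r 0.562 to 0.576), and also between the p300/CBP knockdowns and the TIG-3 etoposide controls, which are of different lines (0.439). In IMR-90, r was 0.434 between controls 1 and 2 and controls 3 and 4, 0.347 between controls 1 and 2 and p300/CBP, 0.342 between controls 3 and 4 and FOXF1/2, and 0.395 between controls 5 and 6 and JUN. The Spearman correlation of the differences with transcript length was -0.639 and -0.553 in the p300/CBP knockdown and the TIG-3 etoposide controls, but -0.116 in proliferating TIG-3 cells and -0.270 in the TIG-3 knockdown, so length leaves most of the TIG-3 correlation open. The replicate difference of p300/CBP correlated less with that of controls 3 and 4 (r 0.108), and that of FOXF1/2 less with that of controls 1 and 2 (0.196). Nothing in the labels says what a number marks, or whether each of these knockdowns belongs with 1 pair of controls. The block also ended the call of FOXF2 in the difference (adjusted p = 0.0672).

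Leaving out each library in turn, which assumes that a lone library varies like the other groups, FOXF1/2 in IMR-90 gave 464 (without knockdown 2) to 1703 genes, with 1151 without knockdown 1. Etoposide gave 1578 (without proliferating control 1; 2008 without control 2) to 4237, and FOXF1/2 in TIG-3 gave 2400 (without knockdown 1; 2788 without knockdown 2) to 4880. The difference gave 374 (without TIG-3 knockdown 1) to 851 genes and 4 to 8 lists. The overlaps ranged from 106 to 518 (p300/CBP and FOXF1/2), 266 to 1026 (FOXF1/2 in both lines), 191 to 606 (FOXF1/2 and JUN), each lowest without FOXF1/2 knockdown 2, and 528 to 1508 (opposite in TIG-3). The median of induced genes ranged from -0.0441 to 0.0152 under FOXF1/2 and from -0.78 (without JUN knockdown 2, unadjusted p = 0.00245) to -0.16 under JUN knockdown. Single genes turned without p300/CBP knockdown 1 (CXCL2, -2.31, against 0.85 without knockdown 2). Under JUN knockdown, without control 5, KIF20A was at 0.0128 (lowest -4.16, without control 6), TK1 at 1.77 (-1.44, without control 6), MKI67 at 0.37 (-4.75, without JUN knockdown 1) and UBE2C at 0.0408 (-3.57, without control 6).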

Other observations

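The test of the hypothesis below was set before its result was seen; the comparison of control sets, the reading of CDKN2A, CDKN1A, CD68 and KRT19 and the test of shared controls were chosen after.

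The cell cycle inhibitor genes CDKN2A and CDKN1A were chosen after their values were seen. CDKN2A rose by 1.19 under p300/CBP and 1.41 under FOXF1/2 knockdown in IMR-90 (SE 0.23 each), by 0.79 with etoposide (SE 0.12) and by 1.18 with FOXF1/2 knockdown in TIG-3 (SE 0.12), and did not pass under JUN knockdown (-0.08, SE 0.28, adjusted p = 0.853). CDKN1A rose under JUN knockdown (0.79, SE 0.23, adjusted p = 0.0198), with etoposide (0.77, SE 0.10) and with FOXF1/2 knockdown in TIG-3 (0.37, SE 0.10), and did not pass under p300/CBP (0.09, SE 0.20, adjusted p = 0.753) or FOXF1/2 knockdown in IMR-90 (-0.31, SE 0.20, adjusted p = 0.326). CD68, a lysosomal gene of macrophages that fibroblasts express too, made up most of the blood marker sum; it fell by 3.36 (SE 0.36) under JUN knockdown and rose with etoposide, from 45.6 ± 2.37 to 112 ± 9.58 CPM. KRT19, a keratin gene, made up most of the epithelial marker sum in TIG-3 and rose by 1.52 (SE 0.14) under FOXF1/2 knockdown there.

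IMR-90 controls 5 and 6 differed from controls 1 to 4 in 2594 of 14163 genes, 1279 higher and 1315 lower. FOXF1 was lower in controls 5 and 6 (-1.05, adjusted p = 0.0224), as was JUNB (-1.04, adjusted p = 0.0355), and CREBBP was higher (0.72, adjusted p = 0.0379). Between pairs of controls 1 to 4, Pearson's r of log2 CPM across genes was 0.986 to 0.991, and with controls 5 and 6 it was 0.954 to 0.971.

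A hypothesis was that part of the p300/CBP response follows the fall of FOXF1 in that knockdown. It was tested on genes that FOXF1/2 knockdown changed at least 2-fold in TIG-3, in libraries separate from the IMR-90 ones. Under p300/CBP knockdown the 791 lowered genes had a median of -0.50 (160 higher and 304 lower) and the 425 raised genes one of -0.20 (120 higher and 129 lower). The difference of -0.30 lay between the -0.5 set in advance for the hypothesis and the -0.25 set against it, so the test does not decide and the hypothesis stays open.

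In TIG-3, etoposide and FOXF1/2 knockdown called 438 and 541 genes in opposite directions, more than the 259 and 279 of independent calls. With single libraries of the same replicate number, assumed to vary like their groups, and no senescent control in common, 450 or 461 genes were opposite (199 or 190 with independent calls) and 372 or 352 in the same direction (206 or 195). The excess of opposite calls was 1.25 or 1.34 times that of calls in the same direction, but each arm was 1 library and no value for unchanged groups stands beside this ratio, so it excludes nothing. Over all genes the covariance was then -0.014 or 0.0464, against -0.0518 with shared controls and -0.0531 in simulations with no change. Part or all of the excess may come from the shared controls, and this stays open.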
